A study of Mus musculus with 8 samples.

How the data were processed

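Gene-level counts of 8 mouse liver RNA-seq libraries were used, 2 per group (control, SLIT2, APAP and SLIT2+APAP), with libraries prepared from total RNA by a directional kit (MGIEasy RNA Directional Library Prep Kit). The deposited table holds counts as whole numbers, not scaled, for 23006 Ensembl gene identifiers in 1 column per library, and all 8 columns were used. The authors' processing notes name STAR 2.5.4, Cufflinks, Cuffdiff 2.2.1 and the mouse build mm10, without saying what each did. The counting step, annotation release, handling of reads that map to several places and strand setting are not given in the sources used here. Of 93 values of at least 1000000, 72 end in 0, so the largest counts appear rounded to 6 digits. Symbols, coordinates, biotypes and GC content came from the GENCODE M21 annotation on GRCm38, the assembly that mm10 names, and matched 22329 identifiers (97.1%).

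Total counts per library ran from 60.8 to 100.5 M (1 M is 1000000 counts). Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Where both libraries of a group had 0 counts, a fold is a lower bound against a floor of 3 counts over the group, and where a group held 1 to 3 counts a ratio with its 95% counting interval is given. Counts per 1000000 counts (CPM) were computed on TMM-scaled library sizes.

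Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 4 groups (16876 genes), libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 8 libraries with robust estimation and the newer, non-legacy fit (legacy = FALSE, which is not the default of the function in this version). This left 4 residual degrees of freedom, a common dispersion of 0.112 and a median prior of 3.98 degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The 5 comparisons were APAP against control, SLIT2 against control, SLIT2+APAP against APAP, SLIT2+APAP against control, and the interaction, the effect of SLIT2 with APAP minus that without it. A count of genes changed by APAP and then called in the opposite direction with SLIT2 was compared with 100 simulated data sets without a SLIT2 effect, because both comparisons use the APAP libraries.

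A total of 30 gene lists covering liver functions, stress responses, cell types, zonation, the clock, SLIT and ROBO signalling and sex-dependent genes was fixed before the data were examined, as were the groups, tests and most alternatives. Lists with at least 5 measured members (29 lists) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison. Camera compares a list with the other genes. With the correlation estimated per list, no list passed in any of the 4 comparisons. Member counts are given over all genes tested and adjusted over the list alone. Named genes followed a rule fixed in advance. It took the 6 largest rises and 6 largest falls among called genes with at least 5 CPM in the higher group, no overlap between the groups and an informative symbol. It also took up to 4 members of each list with the smallest p, Slit2, Robo1, Robo2 and Robo4, and the 6 interaction genes with the smallest p. Other members of lists are named where they make up a count, and the values of a few members are not reported here.

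Alternatives fixed in advance were DESeq2 median-of-ratios factors in edgeR, library totals only, no count filter, at least 10 CPM in 2 libraries, DESeq2 1.42.0 with its own filtering, the legacy edgeR fit, a fold of at least 2, only the 4 libraries compared, each library left out in turn, a replicate block where numbers are shared, and for lists an estimated correlation and fry. Where a group was left with 1 library, that library was assumed to vary like the other groups. Chosen after seeing the data were fits without the 13 mitochondrially encoded genes, without the SLIT2 libraries, with offsets removing each library's trend with GC content, and with protein-coding genes only. Gene families in the closing part were also chosen after seeing the data.

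The tests were tested on simulated data of 16876 genes with 200 changed. In APAP against control edgeR found 58% of genes changed 4-fold and 4% of those changed 2-fold, with 10 false calls among 72, and DESeq2 found 90% and 15% with 54 false calls among 159. In SLIT2+APAP against APAP edgeR found 71% and 7%, with 8 false calls among 86. A raised list was found in each comparison and 0 other lists were called. Genes were drawn independently there, so this does not test list calls where genes vary together. Figures were drawn with matplotlib 3.10.9.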

Results

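RNA of mouse liver was sequenced in 8 libraries, 2 in each of 4 groups. Control mice received phosphate-buffered saline. The SLIT2 group received SLIT2, a secreted ligand of the ROBO receptors, at 2 µg per mouse into the peritoneum over 3 days. The APAP group received acetaminophen (APAP) at 400 mg/kg, and the SLIT2+APAP group received both. Livers were taken 24 h after APAP. An overdose of APAP injures the hepatocytes around the central vein, where Cyp2e1 and other cytochromes turn it into a reactive metabolite. The APAP libraries are numbered 3 and 4 in the labels and those of the other groups 1 and 2. The labels do not say whether the libraries of a group came from separate mice, so the p-values measure the spread between these samples, which may be technical. Abundances are counts per 1000000 counts (CPM) after TMM scaling, as mean ± SD over the 2 libraries of a group, and log2 fold changes carry their standard error.

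Total counts per library ranged from 60.8 to 100.5 M (1 M is 1000000 counts), with group means of 97.95 ± 3.61 M in control (SD, n = 2), 62.05 ± 1.77 M in SLIT2, 92.25 ± 9.69 M in APAP and 78.7 ± 7.07 M in SLIT2+APAP. The 13 mitochondrially encoded genes took 16.65% ± 0.92 of the counts in control and 14.15% ± 1.06 in APAP. Their share was 64.6% ± 6.22 in SLIT2 and 27.7% ± 3.68 in SLIT2+APAP. Counts outside these genes averaged 22 ± 4.38 M in SLIT2, against 81.7 ± 2.12 M in control. Noncoding genes took 1.09% ± 0.08 of those counts in SLIT2 and 0.2% ± 0.02 in control. The first principal component of log2 CPM held 62.3% of the variance and placed the SLIT2 libraries at 159.4 and 175.7, with the other libraries between -92 and 5.3. The median absolute log2 difference between the 2 libraries of a group was 0.601 in APAP, 0.36 in SLIT2, 0.215 in control and 0.219 in SLIT2+APAP. With 2 libraries against 2, an exact permutation test of a single value cannot go below a two-sided p of 0.333, so differences between groups were tested only by models fitted across all genes.

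**Figure D1:**
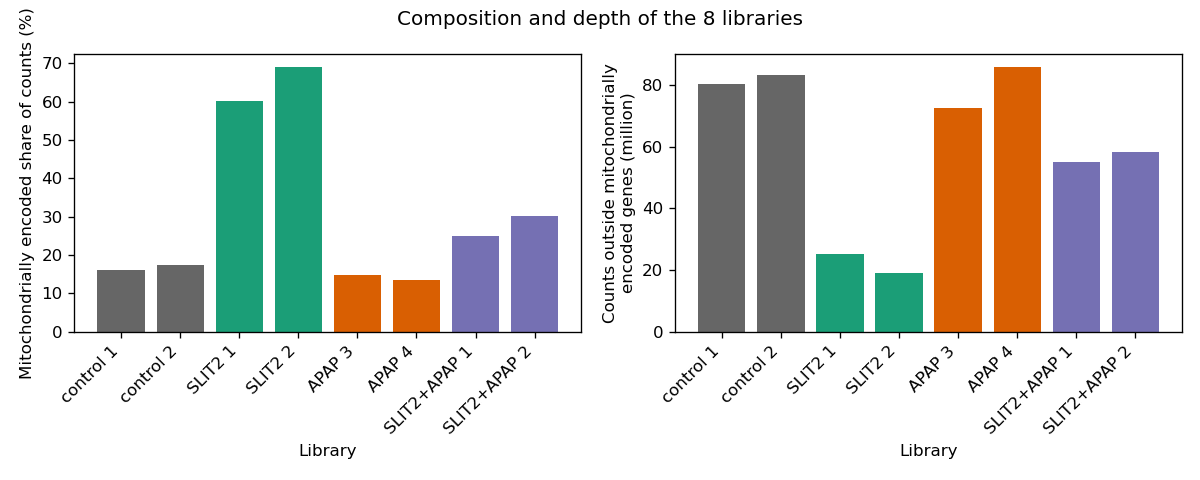
Bars show, for each of the 8 libraries, the share of counts from mitochondrially encoded genes in percent and the counts outside those genes in M (1000000 counts), coloured by group. The SLIT2 libraries have mitochondrial shares of 60.2% and 69% and the smallest non-mitochondrial counts, 25.1 and 18.9 M.

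APAP against control asks what the toxic dose alone did to liver transcripts. At 24 h, immediate early transcription factors stood far above control. Egr1 went from 3.30 ± 0.695 CPM in control to 402 ± 328 CPM in APAP (log2 fold change 6.93 ± 0.83, edgeR adjusted p = 0.03274). Jun rose from 7.87 ± 0.796 to 348 ± 249 CPM and Fos from 1.17 ± 0.102 to 51.0 ± 15.5 CPM. Btg2, an antiproliferative p53 target, had the smallest edgeR adjusted p of the comparison, 0.006499, and rose from 4.41 ± 0.651 to 111 ± 7.57 CPM. Gsta1, a glutathione transferase, rose from 1.09 ± 0.401 to 105 ± 70.7 CPM, and Lgr5, a Wnt target of hepatocytes around the central vein, fell from 7.30 ± 0.433 to 0.841 ± 0.254 CPM. On GRCm38 these protein-coding genes lie on chromosome 18 from 34859823 to 34864984 (Egr1, ENSMUSG00000038418), chromosome 1 from 134075170 to 134079120 (Btg2, ENSMUSG00000020423), chromosome 9 from 78230656 to 78242684 (Gsta1, ENSMUSG00000074183) and chromosome 10 from 115450311 to 115587780 (Lgr5, ENSMUSG00000020140).

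Among the fixed lists, all 11 immediate early genes had a positive fold change with APAP, and 5 of them (Fos, Jun, Junb, Egr1, Ier2) rose over all genes tested, 11 when adjusted over the list alone. The list passed limma camera as higher (adjusted p = 1.266e-18, and adjusted p = 0.3297 with an estimated correlation). Of 18 p53 targets, Btg2 and the stress cytokine Gdf15 rose and 16 did not pass, with 8 up and 1 down adjusted over the list alone (camera adjusted p = 1.963e-05, and adjusted p = 0.4048 with an estimated correlation). The median log2 difference of this list from the control mean was 1.61 in APAP 3 and 0.17 in APAP 4. The size of the list's rise therefore rests mostly on APAP 3, while Btg2 stood at 116.11 and 105.4 CPM in these libraries. Gdf15 stood at 3.65 ± 0.388 CPM in control and 153 ± 124 CPM in APAP. Of 18 genes of the unfolded protein and integrated stress response, Herpud1 rose from 199 ± 1.37 to 642 ± 184 CPM, with 9 up and 1 down adjusted over the list alone (camera adjusted p = 1.963e-05, and adjusted p = 0.3297 with an estimated correlation). No gene of the 10 in the heat shock list passed over all genes, 3 rose adjusted over the list alone, and the list passed camera as higher (adjusted p = 0.009236, and adjusted p = 0.4786 with an estimated correlation). That call was lost without APAP 3 (camera adjusted p = 0.1173).

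The acute phase list, plasma proteins the liver makes in inflammation, had a positive fold change for all of its 22 members. Itih3 rose from 516 ± 65.5 to 1608 ± 78.3 CPM and the other 21 did not pass, while 14 rose adjusted over the list alone (camera adjusted p = 8.615e-13, and adjusted p = 0.4048 with an estimated correlation). Lcn2, at 21.0 ± 9.18 CPM in control and 561 ± 309 CPM in APAP, did not pass over all genes (edgeR adjusted p = 0.05177). Of 23 NRF2 targets and glutathione genes, Gsta1 rose, and 8 did adjusted over the list alone (camera adjusted p = 3.619e-05, and adjusted p = 0.4271 with an estimated correlation). Neutrophil markers (11 genes) and cytokines and chemokines (19 genes) had no member past the threshold over all genes, and 7 and 6 members rose adjusted over the list alone. Both lists passed camera as higher (adjusted p = 0.0005666 and 0.001863, and adjusted p = 0.4048 and 0.4516 with an estimated correlation). The cytokine call was lost without APAP 3 (camera adjusted p = 0.1547). S100a9, a neutrophil calprotectin subunit, was at 0.719 ± 0.0391 CPM in control and 5.93 ± 4.31 CPM in APAP. In the cell cycle list Ccne1 rose (1 of 24, 5 up and 1 down adjusted over the list alone), and the list passed as higher (camera adjusted p = 0.03291, and adjusted p = 0.4048 with an estimated correlation). Without control 1, SLIT2 2 or APAP 4 the camera adjusted p of this list was 0.08537, 0.06064 and 0.2138.

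Pericentral Wnt targets passed camera as lower (adjusted p = 5.143e-05, and adjusted p = 0.4048 with an estimated correlation), with 10 of 11 fold changes negative. Lgr5 fell over all genes tested, and 4 members did adjusted over the list alone. Oat was at 867 ± 61.4 CPM in control and 179 ± 110 CPM in APAP (edgeR adjusted p = 0.07794). Glucuronidation and sulfation genes passed as lower with no member past the threshold over all genes and 2 of 15 lower adjusted over the list alone (camera adjusted p = 0.03281, and adjusted p = 0.4607 with an estimated correlation). In bile acid synthesis and transport the uptake carrier Slco1a1 fell from 296 ± 42.7 to 112 ± 5.16 CPM, and the list had 1 up and 4 down adjusted over the list alone (camera adjusted p = 0.03291, and adjusted p = 0.434 with an estimated correlation). The interferon response list passed as lower with 0 of 17 members past the threshold over all genes and 1 up and 2 down adjusted over the list alone (camera adjusted p = 0.01743, and adjusted p = 0.4516 with an estimated correlation). The sex-dependent list passed as lower too, with 0 of 11 over all genes and 1 down adjusted over the list alone (camera adjusted p = 0.03439, and adjusted p = 0.4597 with an estimated correlation), and its median of -0.32 became 0.12 with offsets for GC content. The calls of these last 4 lists were lost on leaving out single libraries. Without control 2 the camera adjusted p was 0.0512 for glucuronidation, 0.05058 for bile acids, 0.08813 for interferon and 0.1134 for the sex-dependent list. Without APAP 4 it was 0.08907 for glucuronidation, 0.2138 for interferon and 0.2108 for the sex-dependent list, and without APAP 3 it was 0.1173 for glucuronidation, 0.1518 for bile acids and 0.05162 for the sex-dependent list. SLIT2 2 also decided the bile acid (0.05428) and sex-dependent (0.06844) calls, and SLIT2+APAP 1 the sex-dependent call (0.05585). With offsets for GC content the camera adjusted p was 0.3673 for glucuronidation and for the sex-dependent list and 0.05803 for bile acids. The drug-metabolising P450 genes (16) and the hepatocyte genes (22) had no member past the threshold in either count (camera adjusted p = 0.7143 and 0.7563). The P450 median was -0.07 and the mean 0.1, and the median was 0.02 with library totals only and 0.01 with GC offsets. Of 13 monocyte and recruited macrophage markers Cd68 rose from 2.56 ± 0.5 to 17.0 ± 9.63 CPM, with 4 up and 1 down adjusted over the list alone (camera adjusted p = 0.09023). This list passed as higher without APAP 3 (camera adjusted p = 0.03125), as did cholangiocyte markers (0.1445 with all libraries, 0.006863 without APAP 3). The clock list (0.1798) passed as higher without control 2 (0.0005367) and endothelial markers (0.7563) without APAP 4 (0.02886). Cell death (0.09242) passed as higher without APAP 4 (0.001863) and with GC offsets (0.01817).

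The 6 largest falls against control were skeletal muscle genes. Ckm, the muscle creatine kinase, was at 99.2 ± 114 CPM in control and 0.0610 ± 0.0725 CPM in APAP, and Mb, myoglobin, was at 89.2 ± 103 and 0.0520 ± 0.0323 CPM. In control 1 alone Ckm stood at 179.72 CPM, in control 2 at 18.7 CPM and in the other libraries at 0.2 CPM or lower. The falls of Ckm, Mb and Myh4 rest on a level seen only in the control libraries, which differed between them. Myh2 was at 0 in both APAP libraries, at least 1008-fold lower than in control against a floor of 3 counts over the group. For Xirp2 the ratio of control to APAP was 2138 (95% counting interval 383.3 to 84480) and for Ckmt2 it was 1913 (529.3 to 15800). Myh4 was at 40.7 ± 46.2 CPM in control and 0.0284 ± 0.0127 CPM in APAP. Of the 6 largest rises, Sprr1a had a ratio of APAP to control of 492.2 (135.9 to 4070), and Rsc1a1 was at 0 in control, SLIT2 and SLIT2+APAP and at 15.6 ± 12.9 CPM in APAP, at least 861.9-fold higher. Rsc1a1 lies inside the Ddi2 gene on the same strand, so its counts are uncertain.

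Over all 16876 genes tested, edgeR called 133 genes with APAP, 56 up and 77 down (42.1% up, and 61.4% up with scaling by library totals only). The call rested on spread estimated from all 8 libraries. Without SLIT2 1, without SLIT2 2 or without both, edgeR called 0 genes (4190, 4190 and 3908 genes at an unadjusted p under 0.05, against 4148 with all libraries), as it did with only the 4 libraries compared (2654), while DESeq2 called 1836. With offsets for GC content the count was 68. The count was 20 without control 1, 4 without SLIT2+APAP 1 or SLIT2+APAP 2, 553 without APAP 3 and 5181 without APAP 4. Of 21 named genes called here, 19 lost the call without either SLIT2+APAP library, which left Btg2 and Fos, and 15 lost it without control 1, 11 without control 2 and 5 without APAP 3.

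**Figure D2:**
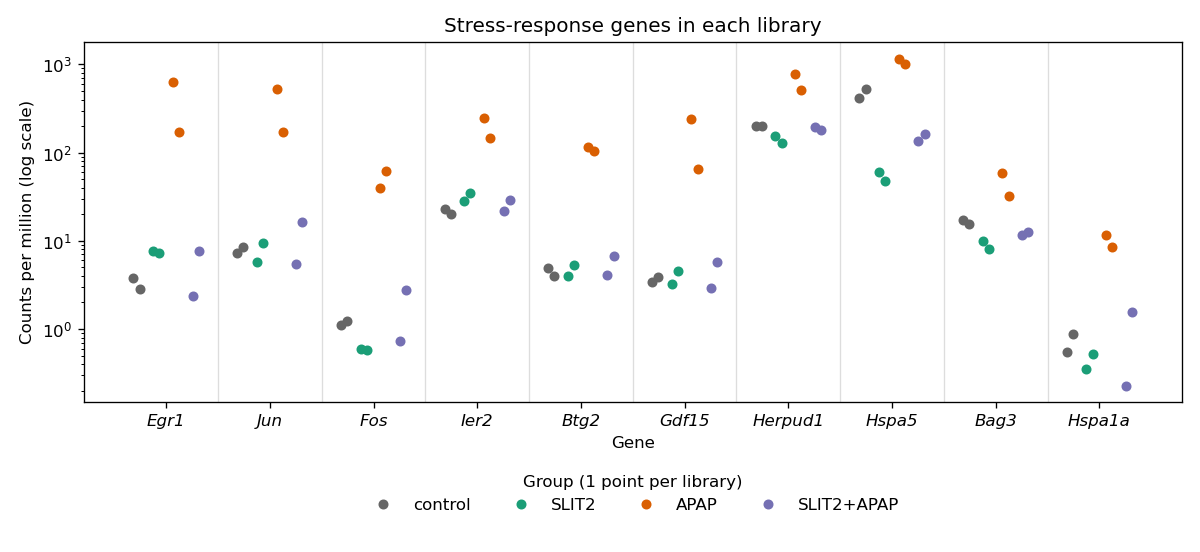
Points show the abundance of 10 stress genes in CPM on a log axis, 1 point per library, coloured by group. Egr1 lies at 634.73 and 170.13 CPM in the APAP libraries and at 2.39 and 7.57 CPM in the SLIT2+APAP libraries.

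SLIT2+APAP against APAP addresses what SLIT2 changed in mice given the toxic dose. The immediate early and stress genes called higher with APAP fell in SLIT2+APAP. Egr1 fell from 402 ± 328 to 4.98 ± 3.66 CPM (log2 fold change -6.33 ± 0.81, edgeR adjusted p = 0.006407), and Btg2 fell from 111 ± 7.57 to 5.36 ± 1.83 CPM (-4.37 ± 0.32, edgeR adjusted p = 0.004034). Hspa5, the main chaperone of the endoplasmic reticulum, fell from 1091 ± 96.2 to 150 ± 18.1 CPM, below the 473 ± 84.4 CPM of control. Fga, the fibrinogen alpha chain, fell from 5588 ± 432 to 629 ± 222 CPM. Lgr5 rose from 0.841 ± 0.254 to 4.96 ± 1.42 CPM, and Gsta1 was at 98.0 ± 35.8 CPM in SLIT2+APAP beside 105 ± 70.7 CPM in APAP. The mitochondrial share was 27.7% ± 3.68 in SLIT2+APAP and 14.15% ± 1.06 in APAP.

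Of the 11 immediate early genes, 7 fell over all genes tested (Fosb, Fos, Jun, Junb, Myc, Egr1 and Ier2) and 11 adjusted over the list alone (camera adjusted p = 8.897e-11, and adjusted p = 0.6071 with an estimated correlation). All 18 genes of the unfolded protein and integrated stress response had a negative fold change. Of these, 9 fell, among them Herpud1 (642 ± 184 to 187 ± 8.37 CPM), Dnajb9 (59.7 ± 2.69 to 12.6 ± 0.230 CPM) and Xbp1 (233 ± 40.9 to 93.4 ± 16.4 CPM), and 13 fell adjusted over the list alone (camera adjusted p = 5.222e-08, and adjusted p = 0.2666 with an estimated correlation). All 10 heat shock genes had a negative fold change, with Hspa1a, Bag3 and Hsph1 past the threshold and 6 adjusted over the list alone (camera adjusted p = 0.000337, and adjusted p = 0.6071 with an estimated correlation). Bag3 fell from 45.6 ± 18.9 to 12.2 ± 0.656 CPM. Of 18 p53 targets, 5 fell (Btg2, Gdf15, Gadd45a, Plk3, Gadd45b), and 8 adjusted over the list alone (camera adjusted p = 0.000274, and adjusted p = 0.6071 with an estimated correlation). Gadd45a and Gadd45b stood at 193.76 and 363.69 CPM in APAP 3 but at 11.28 and 6.17 CPM in APAP 4. In the acute phase list 5 of 22 fell (the fibrinogen chains Fga, Fgb and Fgg, Itih3 and Steap4), and 6 adjusted over the list alone (camera adjusted p = 0.001308, and adjusted p = 0.6071 with an estimated correlation). These 5 lists kept their camera call in each fit that left out 1 library.

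Of 23 NRF2 targets and glutathione genes, 6 fell, including Gstp1 (3386 ± 102 to 1364 ± 187 CPM) and the transporter Abcc3 (35.6 ± 14.8 to 4.59 ± 1.61 CPM), and 7 fell adjusted over the list alone (camera adjusted p = 0.02009, and adjusted p = 0.6071 with an estimated correlation). Hmox1, heme oxygenase, fell from 284 ± 386 to 2.67 ± 0.426 CPM, with 557.02 CPM in APAP 3 and 11 CPM in APAP 4. Without SLIT2 2 or APAP 3 the camera adjusted p of this list was 0.05446 and 0.1675. The hepatocyte list of secreted and metabolic genes had 2 of 22 lower, prothrombin (F2) and fetuin-A (Ahsg), and 1 adjusted over the list alone (camera adjusted p = 0.02009, and adjusted p = 0.6071 with an estimated correlation), and lost its call without APAP 4 (0.1758) or SLIT2+APAP 2 (0.1007). Fatty acid oxidation had 2 of 16 lower, Acaa2 and Ehhadh, and 4 adjusted over the list alone (camera adjusted p = 0.0473, and adjusted p = 0.6071 with an estimated correlation), and lost its call without SLIT2 2 (0.05658), APAP 4 (0.2683) or SLIT2+APAP 2 (0.06503), without the SLIT2 libraries (0.05952) and with protein-coding genes only (0.07762).

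Other lists did not pass camera in this comparison with the main settings. Of 16 drug-metabolising P450 genes, Cyp2a5 rose from 250 ± 5.68 to 812 ± 125 CPM, a gene whose reads are hard to separate from those of Cyp2a4, and 5 fell, including Cyp2e1, Por and Cyp2c29 (3 up and 5 down adjusted over the list alone, camera adjusted p = 0.2435). Bile acid genes had 1 up, the receptor Nr1h4, and 4 down, including the export pump Abcc2 (163 ± 46.9 to 57.1 ± 2.65 CPM), with 2 up and 5 down adjusted over the list alone (camera adjusted p = 0.2435). Neutrophil markers went both ways: Mpo and Cxcr2 rose and S100a9 fell from 5.93 ± 4.31 to 1.07 ± 0.270 CPM, with 2 up and 6 down adjusted over the list alone (camera adjusted p = 0.2973). Cytokines had 2 of 19 lower, Cxcl10 and Icam1, and 6 adjusted over the list alone (camera adjusted p = 0.1672). In the interferon response Ifi44, Ifit1 and Gbp3 rose and Oasl1 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.2973, median 0.07, mean -0.1). Cholangiocyte markers had 3 of 8 lower, Sox9, Epcam and Cldn4, the last at 0 in both SLIT2+APAP libraries and at least 11.3-fold lower, with 4 adjusted over the list alone (camera adjusted p = 0.064). Of 15 glucuronidation and sulfation genes Ugt1a6a, Ugt1a1 and Ugt1a9 fell, and 4 adjusted over the list alone (camera adjusted p = 0.1301). The fallen genes share exons with Ugt1a8, which is outside the list and rose, so how reads divide between them is uncertain. Summed over the Ugt1a genes, abundance was 535.63 and 587.93 CPM in the APAP libraries and 337.91 and 260.26 CPM in SLIT2+APAP. Ugt1a1 alone went from 301.93 and 367.9 to 86.12 and 42.64 CPM. Among 11 pericentral Wnt targets Lgr5 rose, with 2 up and 1 down adjusted over the list alone (camera adjusted p = 0.2435), and of 10 periportal genes Sdsl and Hsd17b13 fell, with 1 up and 3 down adjusted over the list alone (camera adjusted p = 0.2973). Of the remaining cell-type lists, C1qb fell among Kupffer markers, Trem2 rose and Cd68 fell among monocyte and recruited macrophage markers, and Tagln and Sparc fell among stellate cell and matrix genes (camera adjusted p = 0.219, 0.2435 and 0.3567), with 0, 1 up and 3 down, and 2 down adjusted over the list alone. The DNA replication genes Mcm3, Mcm5 and Pcna and the cyclin Ccne1 fell and the survivin gene Birc5 rose among 24 cell cycle genes, with 2 up and 6 down adjusted over the list alone (camera adjusted p = 0.3567). Some lists that did not pass with all libraries passed under other settings. Cytokines passed as lower without APAP 4 or SLIT2+APAP 2 (camera adjusted p = 0.01678 and 0.026), and cholangiocyte markers without control 2 or APAP 3 (0.04712 and 0.01066). Glucuronidation passed as lower without APAP 3 or SLIT2+APAP 1 (0.04365 and 0.03997) and with GC offsets (0.002945). Pericentral Wnt targets passed as higher without APAP 3 or SLIT2+APAP 2 (0.01066 and 0.02191). Without APAP 3, periportal genes passed as lower (0.04797) and endothelial markers as higher (0.8094 with all libraries, 0.04365). Lipid and cholesterol synthesis (0.1301) passed as lower without SLIT2+APAP 1 (0.03573).

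The largest rises were in Atp6v0c-ps2, Kat6b, Ugt1a8, Lrrc71, Tmod1 and Sardhos. Atp6v0c-ps2 (ENSMUSG00000080242, chromosome 6 from 37806086 to 37806550), a processed pseudogene, went from 0.278 ± 0.00518 to 99.5 ± 21.9 CPM (log2 fold change 8.47 ± 0.39, edgeR adjusted p = 0.0004075). Kat6b, a histone acetyltransferase gene, rose from 0.392 ± 0.201 to 7.72 ± 0.404 CPM. Ugt1a8 rose from 10.6 ± 13 to 198 ± 8.69 CPM, and Ugt1a10 was at 0 in both SLIT2+APAP libraries, at least 509.9-fold lower than in APAP. Genes of the Ugt1a locus share exons, so the division of reads between them is uncertain. Rpl10a-ps1, another processed pseudogene (ENSMUSG00000084416, chromosome 1 from 64993951 to 64994604), fell from 104 ± 12.3 to 0.144 ± 0.203 CPM, and Clasp1 and Rsc1a1 were at 0, at least 369.3-fold and 855.3-fold lower. Sardhos is annotated antisense to Sardh, and how strand was used in counting is not given in the sources used here. Fosb and Necab2 completed the 6 largest falls, at 7.79 ± 10.4 and 10.6 ± 14.4 CPM in APAP and under 0.1 CPM in SLIT2+APAP.

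In this comparison edgeR called 2351 of 16876 genes, 1061 up and 1290 down (45.1% up, and 61% up with scaling by library totals only), with 5591 at an unadjusted p under 0.05, and DESeq2 called 3532. Fitting only the 4 libraries compared left 1 called gene, Atp6v0c-ps2 (3915 at an unadjusted p under 0.05), and leaving out the SLIT2 libraries left 1666, 1579 of them shared with the full fit. The count was 21 without SLIT2+APAP 2, 177 without SLIT2+APAP 1, 972 without control 1, 982 without control 2, 1522 without SLIT2 2 and 6133 without APAP 4. Of 79 named genes called here, 73 lost the call without SLIT2+APAP 2, 62 without SLIT2+APAP 1, 37 without control 1, 36 without control 2, 25 without SLIT2 2, 22 without SLIT2 1, 12 without APAP 3 and 5 of 78 without APAP 4. Btg2, Fos, Kat6b, Lrrc71, Rpl10a-ps1 and Atp6v0c-ps2 kept it without SLIT2+APAP 2.

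Of the 133 genes called in APAP against control, 78 were called in the opposite direction in SLIT2+APAP against APAP and 0 in the same direction. Of these, 46 were up with APAP and then down, where independent lists would share 4.281, and 32 were down and then up, where they would share 4.841. The APAP libraries enter both comparisons with opposite signs, which produces a negative relation without any effect. The covariance of the log2 CPM differences across genes was -0.653 (r = -0.61), of which the spread of the shared APAP libraries accounted for -0.325. In 100 simulated data sets with no SLIT2 effect, r across genes ran from -0.255 to -0.206 and between 0 and 4 genes were called in opposite directions. SLIT2+APAP against APAP called 0 to 5 genes there, which holds that count near 0, so the simulation does not test the 78. The simulated data did not match the real libraries, with a median of 2157 genes called for APAP against 133, so the comparison of r is limited too. Genes are not independent replicates. The count of 78 was 2 without control 1, 19 without control 2, 3 without SLIT2+APAP 1 or SLIT2+APAP 2, 418 without APAP 3 and 3880 without APAP 4. It was 34 with offsets for GC content. It was 0 without either SLIT2 library or both, where no APAP gene was called by edgeR (3908 at an unadjusted p under 0.05 without both), and 1099 with DESeq2.

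SLIT2 against control asks what SLIT2 did without the toxic dose. Genes of hepatocyte function were widely lower in the SLIT2 libraries as scaled by TMM. F2 fell from 968 ± 36.9 to 60.5 ± 9.72 CPM (log2 fold change -4.00 ± 0.30, edgeR adjusted p = 0.0001002), Cyp2e1 from 2932 ± 99.1 to 395 ± 130 CPM, and Fabp1, the liver fatty acid binding protein, from 3996 ± 328 to 240 ± 145 CPM. Slit2 itself (ENSMUSG00000031558, chromosome 5 from 47983138 to 48307733) rose from 0.107 ± 0.0174 to 1.38 ± 0.130 CPM (3.67 ± 0.49, edgeR adjusted p = 0.00057), and its receptor gene Robo1 from 2.52 ± 0.0378 to 5.11 ± 0.819 CPM. All of these changes coincide with a mitochondrial share of 64.6% ± 6.22 in SLIT2 and 16.65% ± 0.92 in control, and with a noncoding share of 1.09% ± 0.08 and 0.2% ± 0.02. CPM are shares of all counts, so a larger mitochondrial share leaves less for other genes. TMM scaling takes most genes as unchanged, while 54.9% of those tested were called. No fit was scaled to the totals outside mitochondrially encoded genes without TMM, so the size of these falls is uncertain.

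Of 22 hepatocyte genes 18 fell, and 19 adjusted over the list alone (camera adjusted p = 6.531e-07). Fatty acid oxidation had 12 of 16 lower and Ppara and Ppargc1a, transcriptional regulators of that pathway, higher, with the same numbers adjusted over the list alone (camera adjusted p = 0.0009355). Ppara rose from 23.4 ± 0.122 to 77.8 ± 10.1 CPM. In the acute phase list 13 of 22 fell, 15 adjusted over the list alone (camera adjusted p = 0.0009355). Among P450 genes 10 of 16 fell, 11 adjusted over the list alone (camera adjusted p = 0.002615), including Cyp3a11 (2338 ± 28.4 to 131 ± 88.0 CPM). Of the glucuronidation and sulfation genes 11 of 15 fell and Sult5a1 rose, also adjusted over the list alone (camera adjusted p = 0.02029). Ugt1a1, Ugt1a6a and Ugt1a9 are among those that fell, and their reads are hard to divide from those of other Ugt1a genes. The sum of the Ugt1a genes was 328.58 and 411.46 CPM in control and 199.16 and 217.39 CPM in SLIT2. NRF2 targets and glutathione genes had 13 of 23 lower and Mafg and Slc7a11 higher, with the same numbers adjusted over the list alone (camera adjusted p = 0.02835). Heat shock genes fell in 7 of 10 cases (7 adjusted over the list alone, camera adjusted p = 0.01231) and unfolded protein and integrated stress response genes in 8 of 18 (8 adjusted over the list alone, camera adjusted p = 0.02835). Markers of Kupffer cells, the resident liver macrophages, fell in 8 of 11 cases, 8 adjusted over the list alone (camera adjusted p = 0.009229), among them C1qa (27.3 ± 5.39 to 2.70 ± 0.540 CPM). For each of these 9 lists the adjusted p was 0.6203 with an estimated correlation. With protein-coding genes only, the NRF2 and unfolded protein lists lost their calls (camera adjusted p = 0.06117 and 0.06067).

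The remaining lists did not pass camera in SLIT2 against control with the main settings. Markers of T, B and NK cells had 5 of 13 higher, and 4 adjusted over the list alone (camera adjusted p = 0.1957). Neutrophil markers had 3 of 11 higher, with Cxcr2 rising from 1.64 ± 0.0285 to 26.6 ± 0.376 CPM, and 3 adjusted over the list alone (camera adjusted p = 0.1312). Monocyte and recruited macrophage markers had 3 up and 4 down of 13, also adjusted over the list alone (camera adjusted p = 0.6473), and endothelial markers 3 up and 4 down of 12, also adjusted over the list alone (camera adjusted p = 0.5825). Stellate cell and matrix genes had 6 of 15 lower in both counts (camera adjusted p = 0.2565), and cholangiocyte markers had 2 up and 1 down of 8 in both counts (camera adjusted p = 0.8471), with a median of 0.18 and a mean of -0.46. Erythroid genes had 5 of 6 lower in both counts (camera adjusted p = 0.07025), where Hba-a1 and Hba-a2 have near-identical sequences. The erythroid list passed as lower without control 1 (camera adjusted p = 0.03617), APAP 3 (0.02901), APAP 4 (0.02711), SLIT2+APAP 1 (0.03383) or SLIT2+APAP 2 (0.03434). With the replicate block, in the 6 libraries without APAP, it passed too (0.02721), and neutrophil markers passed as higher (0.0404). Of 13 exocrine pancreas markers 3 were measured, too few for a list test, and Cela1 and Cela2a fell. Among 13 clock genes Per1, Per2, Per3, Tef, Ciart and Bhlhe41 rose and Cry1, Clock and Arntl fell, in both counts (camera adjusted p = 0.4378). Per2 rose from 7.65 ± 5.52 to 34.5 ± 3.72 CPM, and Arntl, its activator, fell from 4.16 ± 2.98 to 0.273 ± 0.0525 CPM. In SLIT and ROBO signalling 6 of 11 rose (Slit2, Robo1, Robo2, Srgap1, Srgap2, Cxcr4) and Cxcl12 fell, in both counts (camera adjusted p = 0.1957). Robo2 rose from 0.738 ± 0.0180 to 2.15 ± 0.391 CPM, and Robo4 stood at 2.33 ± 0.584 and 6.71 ± 0.661 CPM (edgeR adjusted p = 0.09774). Bile acid genes had 7 of 15 lower in both counts (camera adjusted p = 0.1957), the interferon list 1 up and 6 down of 17, with 1 up and 5 down adjusted over the list alone (camera adjusted p = 0.4378), and cytokines 1 up and 1 down of 19, with 1 down adjusted over the list alone (camera adjusted p = 0.9311). Cell cycle genes had 7 up and 5 down of 24, with 5 up and 5 down adjusted over the list alone (camera adjusted p = 0.5825). The p53 list had 2 up and 5 down of 18, with 1 up and 4 down adjusted over the list alone (camera adjusted p = 0.5825), and cell death 3 up and 7 down of 16 in both counts (camera adjusted p = 0.4926). Lipid and cholesterol synthesis had Srebf1 up and Srebf2 down of 17, with 1 down adjusted over the list alone (camera adjusted p = 0.9202). Pericentral Wnt targets had 2 of 11 lower, Oat and Lect2, in both counts (camera adjusted p = 0.2543), and periportal genes Uroc1 up and Agxt and Hsd17b13 down of 10, with 2 down adjusted over the list alone (camera adjusted p = 0.1957). The sex-dependent list had 5 of 11 lower in both counts (camera adjusted p = 0.1957). No immediate early gene of 11 passed in either count (camera adjusted p = 0.9293, median 0.34, mean -0.07), with Egr1 at 3.30 ± 0.695 CPM in control and 7.47 ± 0.322 CPM in SLIT2.

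The largest rises in the SLIT2 libraries were in Chrna4, Esp6, Sardhos, Galnt17, Duxf3 and Ffar2, between 0.146 ± 0.0129 and 0.455 ± 0.0703 CPM in control and between 15.5 ± 3.97 and 51.5 ± 33.3 CPM in SLIT2. The rise of Chrna4, which was at 21.8 ± 27.5 CPM in SLIT2, lost its call without control 1 or SLIT2 2. Rpl10a-ps1 was at 77.0 ± 3.04 CPM in control and 0 in both SLIT2 libraries, at least 3155-fold lower, and Ugt1a10 at least 299.7-fold lower. The other 4 of the largest falls were the muscle genes Ckm, Fabp3, Pgam2 and Myl2, the last 3 at 0 in SLIT2 and at least 874.6-fold, 319.4-fold and 310-fold lower, with a control to SLIT2 ratio for Ckm of 5794 (95% counting interval 1604 to 47850).

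Here edgeR called 9266 of 16876 genes, 4601 up and 4665 down, 54.9% of those tested, with 10250 at an unadjusted p under 0.05. Each fit that left out 1 library gave a count between 6272 and 11672, and a filter at 10 CPM in 2 libraries, which tests fewer genes, gave 4645. Of 118 named genes called here, 20 lost the call without SLIT2 2, 16 without control 1, 14 without control 2 and 10 without SLIT2 1, with 4 lost without SLIT2+APAP 1 or SLIT2+APAP 2, 1 without APAP 4 and 0 without APAP 3.

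**Figure D3:**
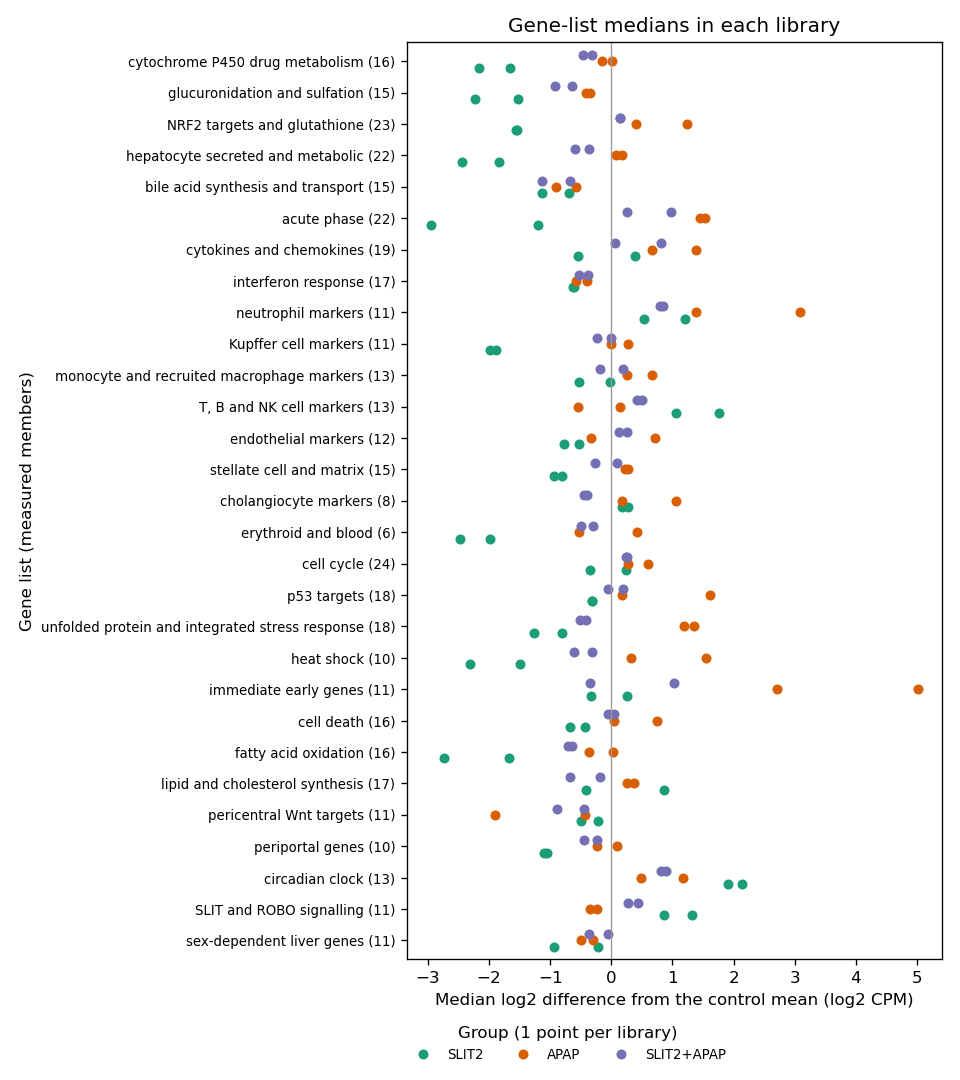
Points show, for each of 29 gene lists and each library outside the control group, the median over the list of the log2 difference from the control mean, coloured by group. The hepatocyte list lies at -1.84 and -2.44 in the SLIT2 libraries and at 0.17 and 0.07 in the APAP libraries. The immediate early list lies at -0.33 and 0.25 in SLIT2 and at 5.01 and 2.71 in APAP.

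SLIT2+APAP against control asks how far mice given both treatments still differed from control mice. Immediate early and p53 genes had no member past the threshold, while several drug-conjugating enzymes were lower than in control and Gsta1 stayed higher. A gene that did not pass is not shown to be at its control level. In simulated data for this comparison edgeR found 73% of genes changed 4-fold and 2% of those changed 2-fold. Gsta1 rose from 1.09 ± 0.401 to 98.0 ± 35.8 CPM (log2 fold change 6.48 ± 0.87, edgeR adjusted p = 0.02532). Ugt2b1 fell from 504 ± 79.6 to 88.8 ± 21.6 CPM (-2.5 ± 0.39, edgeR adjusted p = 0.03107), and Cyp2f2 from 694 ± 4.07 to 220 ± 15.4 CPM. Hspa5 fell from 473 ± 84.4 to 150 ± 18.1 CPM and Asns, asparagine synthetase, from 17.9 ± 6.54 to 1.65 ± 0.520 CPM. The mitochondrial share was 27.7% ± 3.68 and 16.65% ± 0.92.

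Of 15 glucuronidation and sulfation genes Ugt1a6a, Ugt2b38 and Ugt2b1 fell, and 7 adjusted over the list alone (camera adjusted p = 8.318e-06, and adjusted p = 0.598 with an estimated correlation). Ugt1a6a shares exons with other Ugt1a genes, and their sum was 328.58 and 411.46 CPM in control and 337.91 and 260.26 CPM in SLIT2+APAP. Bile acid genes had Slco1a1 lower of 15, and 4 adjusted over the list alone (camera adjusted p = 0.000241, and adjusted p = 0.598 with an estimated correlation). Fatty acid oxidation had Acaa2 and Ehhadh lower of 16, with 1 up and 3 down adjusted over the list alone (camera adjusted p = 0.001092, and adjusted p = 0.6375 with an estimated correlation). The acute phase list passed as higher with 0 of 22 members past the threshold over all genes and 9 up and 2 down adjusted over the list alone, neutrophil markers passed as higher with Cxcr2 up of 11, also adjusted over the list alone, and the hepatocyte list passed as lower with 0 of 22 over all genes and 2 adjusted over the list alone (camera adjusted p = 0.005408, 0.041 and 0.007544, and adjusted p = 0.6375 with an estimated correlation for each). Pericentral Wnt targets, P450 genes and the unfolded protein list passed as lower with 0 of 11, 1 of 16 and 2 of 18 genes down (camera adjusted p = 0.02852, 0.04451 and 0.0332, and adjusted p = 0.6375 with an estimated correlation for each). Adjusted over the list alone the pericentral genes had 0 past the threshold, the P450 genes 1 up and 3 down and the unfolded protein list 1 up and 2 down. Without SLIT2+APAP 1 the camera adjusted p was 0.09242 for the acute phase and 0.1724 for the unfolded protein list. Without SLIT2+APAP 2 it was 0.05054 for neutrophil markers, 0.139 for P450, 0.06917 for the hepatocyte list and 0.1515 for pericentral genes. With protein-coding genes only it was 0.06712 for P450. With the replicate block, in the 6 libraries without APAP, it was 0.06706 for P450 and for the unfolded protein list. Without control 2 it was 0.3433 for P450, 0.05774 for the hepatocyte list and 0.06381 for pericentral genes, and without control 1 it was 0.08042 for neutrophil markers, which also lost the call without the SLIT2 libraries (0.05487).

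The 6 largest rises were in Atp6v0c-ps2 (0.743 ± 0.124 to 99.5 ± 21.9 CPM), Cyp2a4 (0.370 ± 0.220 to 35.6 ± 37.5 CPM), Gsta1, Sardhos, the class I gene H2-Q2 (0.335 ± 0.132 to 5.48 ± 2.67 CPM) and Adam11. Cyp2a4 and Cyp2a5 are near-identical, as are the class I genes, so their counts are uncertain. Of the 6 largest falls, Ugt1a10 was at least 432.6-fold lower and the other 5 were the muscle genes Tnnc2, Tnni2, Ckm, Atp2a1 and Acta1. The cell cycle, cytokine, interferon, endothelial and Kupffer lists had no member past the threshold over all genes (camera adjusted p = 0.3059, 0.2553, 0.2497, 0.4725 and 0.5289). Some lists passed only under other settings. Heat shock (0.0721) passed as lower without control 1, SLIT2 2 or SLIT2+APAP 2 (camera adjusted p = 0.00346, 0.04456 and 0.002738), and the interferon list without APAP 4 (0.04954). Periportal genes (0.1206) passed as lower without control 1, APAP 3 or APAP 4 (0.01725, 0.04193 and 0.04405), and lipid and cholesterol synthesis (0.1206) without control 1 or SLIT2+APAP 1 (0.0004337 and 0.03844). The sex-dependent list (0.1206) passed as lower without control 1 (0.04067) and the erythroid list (0.1206) without SLIT2+APAP 1 (0.01685). The clock list (0.2079) passed as higher without control 2 (0.001102) and the immediate early list (0.4725) without SLIT2+APAP 1 (0.04316). Robo1 stood at 2.52 ± 0.0378 CPM in control and 2.5 ± 0.307 CPM in SLIT2+APAP, beside 0.831 ± 0.117 CPM in APAP, and its rise from APAP passed (log2 fold change 1.58 ± 0.30, edgeR adjusted p = 0.01671). Slit2 was at 0.138 ± 0.0355 CPM in SLIT2+APAP.

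In SLIT2+APAP against control edgeR called 365 genes, 121 up and 244 down (33.2% up, and 68.5% up with scaling by library totals only), with 3445 at an unadjusted p under 0.05. With library totals only, the median log2 fold change of all genes moved from 0.038 to 0.34 here, from 0.046 to 0.16 in APAP against control, from -0.005 to 0.11 in SLIT2 against control and from -0.06 to 0.12 in SLIT2+APAP against APAP. Without SLIT2 1, SLIT2 2 or both, 3 genes were called, while only the 4 libraries compared gave 4246 and DESeq2 1455. The count was 2 without SLIT2+APAP 2, 4 without SLIT2+APAP 1, 19 without control 1, 150 without control 2, 2558 without APAP 3 and 2456 without APAP 4. Of 24 named genes called here, 23 lost the call without either SLIT2 or either SLIT2+APAP library, which left Atp6v0c-ps2, and 19 lost it without control 1 and 16 without control 2.

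The effect of SLIT2 was compared with and without APAP. Genes called up in both SLIT2 comparisons numbered 812, where independent lists would share 289.3, and genes called down in both numbered 776, where they would share 356.6. Opposite calls numbered 52 and 47, where independent lists would share 351.7 and 293.3. The fold changes correlated across genes at r = 0.38 (rho = 0.39), and these comparisons share no library. In both of them the group given SLIT2 also had the higher mitochondrial share (64.6% against 16.65%, and 27.7% against 14.15%). The overlap therefore cannot tell an effect of SLIT2 from a difference in library content that follows this share. The test of the difference between both SLIT2 effects, the interaction of SLIT2 and APAP, called 4867 genes, 2615 higher and 2252 lower, with 7332 at an unadjusted p under 0.05. For Slit2, Robo1, Robo2 and Robo4 the interaction did not pass (edgeR adjusted p = 0.06243, 0.3207, 0.1957 and 0.06245).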

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

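Of the tests in this part, the one with the mitochondrially encoded genes left out was chosen after its result was seen, and the others before.

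The effect of SLIT2 differed between mice with and without APAP by the interaction test, which called 4867 of 16876 genes. The 6 genes with the smallest p had an edgeR adjusted p of 0.003125 each, and all were lower in the SLIT2 libraries than in every other group. The calcium-binding gene S100a1 had an interaction of 3.99 on the log2 scale (121 ± 11.9 CPM in control, 8.77 ± 1.27 in SLIT2, 82.4 ± 6.79 in APAP, 95.3 ± 8.49 in SLIT2+APAP). The ribosomal gene Rps23 had 3.71, the ubiquitin-like modifier Nedd8 3.57, the tetraspanin Cd151 3.54, the complex I subunit Ndufa1 4.72 and the mannose-binding lectin Mbl2 3.58. These 6 genes kept their call in each alternative that was fitted for the interaction. The count was 1002 without SLIT2+APAP 1, 2081 without SLIT2+APAP 2, 1456 without control 1, 1739 without control 2, 2050 without SLIT2 2 and 8303 without APAP 4.

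The interaction uses the SLIT2 libraries, which set these 6 genes apart. They also gave 9266 called genes against control, 54.9% of those tested, with 60.2% and 69% of counts from mitochondrially encoded genes. With those genes left out, 9563 of 17506 genes tested were called. TMM scaling is a trimmed mean over all genes, which the 13 mitochondrially encoded genes can hardly move. Leaving them out moved the hepatocyte list median from -1.99 to -2.06 and the P450 median from -1.88 to -1.95. This argues against a pull of those counts on TMM scaling. The fit cannot decide whether TMM scaling, which takes most genes as unchanged, holds for these libraries. A lower depth is argued against as the whole cause, since 8676 genes were called with all libraries thinned to 18.9 M non-mitochondrial counts. A gradient in RNA quality or library content that follows the mitochondrial share stays open: across genes, the difference between the SLIT2+APAP libraries correlated with the SLIT2 change at a Pearson r of 0.26 and a rho of 0.38. A correlation above 0.3 was set as going with it and 0.1 or lower as going against it, without naming the kind. The rho lies above the first bound and the Pearson r between the bounds. A biological effect of SLIT2 also stays open and was not tested apart from it, because the mitochondrial share follows the SLIT2 group and these cannot be told apart.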

How the results depend on the processing

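The fits without the SLIT2 libraries, with offsets for GC content, with protein-coding genes only and without mitochondrially encoded genes were chosen after seeing the data. Against 133, 9266, 2351, 365 and 4867 genes called (APAP against control, SLIT2 against control, SLIT2+APAP against APAP, SLIT2+APAP against control, interaction) and 78 moved back, counts beyond 1.5 times were as follows, and except where the setting tests fewer genes or samples the cause was not tested. Library totals only gave 236 for APAP and 121 moved back, no count filter 205 and 119, the legacy fit 54 and 35, and GC offsets 68 and 34. DESeq2 gave 1836, 3532 for SLIT2+APAP against APAP, 1455 for SLIT2+APAP against control and 1099 moved back. The filter at 10 CPM, which tests fewer genes, gave 4645 for SLIT2. Only the 4 libraries compared gave 0 for APAP by edgeR (2654 at an unadjusted p under 0.05, DESeq2 with all libraries 1836), 1 for SLIT2+APAP against APAP and 4246 for SLIT2+APAP against control. Without the SLIT2 libraries edgeR gave 0 (3908 at an unadjusted p under 0.05) and 3 for APAP and SLIT2+APAP against control, and 0 moved back. The replicate block, in the 6 libraries without APAP, gave 2494 for SLIT2+APAP against control and the same libraries unpaired 2582. Deviations of libraries with the same number correlated between groups at 0.075, -0.071 and -0.015, and the labels share only a number.

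Leaving out 1 library gave 0 to 5181 genes for APAP, 6272 to 11672 for SLIT2, 21 to 6133 for SLIT2+APAP against APAP, 2 to 2558 for SLIT2+APAP against control, 1002 to 8303 for the interaction and 0 to 3880 moved back. The lowest APAP count, 0 by edgeR, came without SLIT2 1 or SLIT2 2 (4190 at an unadjusted p under 0.05 each), and the highest counts for APAP, SLIT2+APAP against APAP, the interaction and moved back came without APAP 4. SLIT2+APAP against control gave 2558 without APAP 3 and 2 without SLIT2+APAP 2, SLIT2+APAP against APAP gave 21 without SLIT2+APAP 2, the interaction gave 1002 without SLIT2+APAP 1, and SLIT2 against control, within 1.5 times throughout, gave 6272 without control 1 and 11672 without APAP 3. Against 14, 9, 8 and 9 lists called, an estimated correlation gave 0, 0, 0 and 0, and fry, which asks another question, gave 1, 21, 1 and 0. No fold change of a named gene and no camera direction of a list reversed, where a change of sign counts only if the value passed before or after. Other summaries did turn. With GC offsets the median of the sex-dependent list in APAP against control went from -0.32 to 0.12. With library totals only, the share of calls that were up in SLIT2+APAP against control went from 33.2% to 68.5%. For single named genes, 5411 values under other settings kept their direction and side of the threshold, 364 newly passed and 276 no longer passed. With 1 library left out the numbers were 3478, 234 and 580. For single lists they were 745, 16 and 80, and with 1 library left out 858, 35 and 35. DESeq2 gave no adjusted p for 7137 genes in APAP against control. The SLIT2 libraries hold 25.1 and 18.9 M counts outside mitochondrially encoded genes, which limits low-abundance genes there most.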

Other observations

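Of the tests in this part, that of parent genes was set before its result was seen, and those of shared reads, GC content, the library gradient and single APAP libraries were chosen after.

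Gene families chosen after seeing the data showed a broad pattern in SLIT2 against control. Of 90 nuclear-encoded respiratory chain genes 82 fell and 1 rose (median log2 fold change -2.83, camera adjusted p = 2.657e-36, and adjusted p = 0.1627 with an estimated correlation), while all 13 mitochondrially encoded genes rose (median 1.83, camera adjusted p = 3.787e-06, and adjusted p = 0.215 with an estimated correlation). Of 82 cytosolic ribosomal protein genes 72 fell (median -2.24, camera adjusted p = 1.699e-27, and adjusted p = 0.1627 with an estimated correlation), and of 39 proteasome subunits 30 fell and 1 rose (median -2, camera adjusted p = 7.212e-12, and adjusted p = 0.1627 with an estimated correlation). All 12 albumin and apolipoprotein genes fell (median -2.27, camera adjusted p = 3.636e-06, and adjusted p = 0.1958 with an estimated correlation). The median fold change was 2.48 for long intergenic RNA genes, 1.85 for antisense genes, 1.82 for processed pseudogenes and -0.13 for protein-coding genes. From the fifth of genes with the shortest exons to that with the longest, medians were -0.45, -0.43, -0.06, 0.08 and 0.49. From the fifth of genes with the lowest mean abundance over the libraries to the highest, they were 1.29, 0.69, -0.05, -0.38 and -0.95. Falls of abundant families and rises of scarce noncoding genes go in the direction of this trend, and they were not separated from it.

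Major urinary protein genes, which carry pheromones and are near-identical in sequence, were lower in each treated group. In SLIT2 against control 15 of 17 fell and 1 rose (median -4.03, camera adjusted p = 1.682e-07, and adjusted p = 0.1958 with an estimated correlation). With APAP all 17 fold changes were negative and 0 passed by edgeR over all genes (median -1.72, camera adjusted p = 2.284e-11, and adjusted p = 0.2496 with an estimated correlation). In SLIT2+APAP against control 4 fell and all 17 were negative (median -2.26, camera adjusted p = 1.106e-19, and adjusted p = 0.1527 with an estimated correlation). Skeletal muscle genes were called lower than in control in 12 of 16 cases with APAP, 15 of 16 with SLIT2 and 14 of 16 with both. They took 0.139% of the scaled counts in control 1, 0.016% in control 2 and 0.001% or 0.002% in the other libraries. Acta1 stood at 211.81 CPM in control 1, 25.67 CPM in control 2 and under 0.4 CPM in the other libraries. These calls rest on a level seen only in the control libraries, which differed between them. They cannot be read as an effect of each treatment.

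Of the stress genes in 4 lists (immediate early, p53, unfolded protein and heat shock), the 24 called lower in SLIT2+APAP than in APAP had a median log2 fold change of -3.11, beside 3.16 in APAP against control and 0.22 in SLIT2+APAP against control. These genes were picked for high values in the APAP libraries, so a positive median in APAP against control is partly built in. A trend with GC content is argued against as the whole cause of the fall, since the median of -3.11 became -2.99 with GC offsets. The library gradient that sets the SLIT2 libraries apart was read for the 12 immediate early and p53 genes among them. Their median was -4.79, and in SLIT2 against control, where that gradient is larger, it was 0.01 (quartiles -0.6 and 0.42) with 1 up and 0 down. Whole-list medians were -4.28 and 0.34 for immediate early genes and -1.51 and -0.39 for p53 targets. The change in SLIT2 against control varied with abundance. Its median was 1.29 for genes of the lowest mean abundance over the libraries and -0.95 for those of the highest. The 12 immediate early and p53 genes, picked by their fall, stood lower in control than in APAP. Their median in SLIT2 against control therefore cannot decide whether a gradient acting on abundant transcripts lowered them from their APAP level. The library gradient stays open for these genes. For the 12 unfolded protein and heat shock genes the library gradient stays open too. Their median was -2.17, and in SLIT2 against control -0.83 (quartiles -2.34 and -0.64), with 6 called down, and Asns, Dnajb9, Hspa5 and Hsph1 fell at least as far there. A high level in 1 APAP library alone is argued against as the whole cause. Over all 57 tested members of the 4 lists, called or not, the median was -1.91, and it was -1.13 without APAP 3 and -2.39 without APAP 4. In 43 of the 57 both APAP libraries lay above both SLIT2+APAP libraries, in 6 only APAP 3 did and in 4 only APAP 4. APAP 3 was higher than APAP 4 in 46 of the 57, so the size of the fall rests more on APAP 3. A lower response to APAP in mice given SLIT2 may account for the pattern, as may a difference in the dose received or in the time course of injury, and these were not tested.

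In 7 genes, every library of both groups given SLIT2 differed at least 20-fold from every library of the others, with a mean of at least 5 CPM on the higher side: Rpl10a-ps1, Ugt1a10, Gm11808, Gm13835 and Gm20390 lower, and Atp6v0c-ps2 and Gm10175 higher. They are named in part after their values were seen, and the other divisions of the groups of this form gave 1 and 0 such genes. Of the 7, 57.1% are annotated pseudogenes, against 4.4% of genes tested (Fisher's exact test, two-sided p = 0.000116), as reads shared between near-identical copies and placed differently in those libraries would give. A transfer between a copy and its parent would also keep their sum, and it did not stay. Rpl10a-ps1 and Rpl10a together fell from 219.7 CPM in control to 135.7 CPM in SLIT2, and Atp6v0c-ps2 and Atp6v0c from 165.9 to 38.7 CPM. From APAP to SLIT2+APAP these sums went from 244.3 to 171.9 CPM and from 238.6 to 140.1 CPM. The sums are a weak test in SLIT2, where cytosolic ribosomal protein genes as a family also fell (median -2.24). Shared reads therefore stay open. The parents named by the symbols changed by 0.16 of their copies' change, under the bound set against a change in the parents, but only 2 parents could be read and they differ: Rpl10a had -0.07 in SLIT2 against control, and Atp6v0c had -4.36 while its copy had 5.36. A change in the parents therefore stays open too. A sequence variant in the mice given SLIT2 was not tested.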
